A study of Mus musculus with 42 samples.

How the data were processed

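RNA of quadriceps and soleus muscle was hybridised to 1-colour Affymetrix mouse arrays, 1 array per muscle sample. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised. The values used are the log2 expression values that the authors deposited as 1 table of 42 arrays. MAS5 and RMA are named in the submitters' processing notes, without a role or a version. The table holds values on a log2 scale with nearly equal distributions: medians ran from 4.34 to 4.47 and 75th percentiles from 6.32 to 6.52 over the 40 arrays with a group. How the background was corrected, how the arrays were scaled and how probes were summarised are not given in the sources used here. The values were used as deposited, with no further normalization in the main analysis.

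Samples were grouped by the genotype, age and muscle in their labels, which gave 8 groups and 40 arrays. Both arrays of wt adult mouse M2-1 were left out of every comparison because the title and the description of each name different muscles. Arrays of one group come from separate mice by their labels, so the spread between them includes the animals. For arrays, their number limits the precision: groups hold between 4 and 7.

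Of 45101 probe sets, 64 control probe sets were left out. Among the remaining 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none or were not listed there. Probe sets with several symbols or none were not tested by gene. Gene IDs were used to look up current symbols in a gene table of assembly GRCm38.p6, which matched 34754 probe sets (99.4%) and gave 18193 genes. That table served for names and for which genes neighbour each other, and no coordinates are printed because the build behind the deposited table is not named. A probe set was kept when its value exceeded the array's own median on at least 4 arrays of the fit. Each gene was then represented by its probe set with the highest mean. These steps left 11915 genes in quadriceps, 11969 in soleus and 12256 in the paired analysis of both muscles.

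Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 for fits with correlated blocks and jsonlite 2.0.0 to read the labels. The 4 groups of a muscle entered 1 fit and shared 1 estimate of the spread. Contrasts were C3KO minus wt at each age, adult minus young in each genotype, and the difference between both ages in the genotype effect. Soleus minus quadriceps differences were formed within each of 19 mice with both arrays and fitted with limma, for the muscle difference in wt adults and for the genotype effect on it at each age. In all, 13 comparisons were made. Adjusted p values are limma's p values (two-sided) after the Benjamini-Hochberg method, at a threshold of 0.05. Errors given with ± after a log2 change are standard errors.

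Lists of genes, 38 in number, were fixed before the data were examined, as were the groups, the tests, most alternatives and the rule for naming genes. Each list was tested with limma's camera, which asks whether its genes moved more than the other genes tested. The main setting was a preset correlation between genes of 0.01, and the test was repeated with a correlation estimated from the arrays, both adjusted over the 38 lists of a comparison. Of 119 list calls with the preset correlation, 2 held with an estimated correlation, both of heat shock protein genes in quadriceps. Members were also counted at an adjusted p under 0.05 over all genes tested and adjusted over the list alone. Genes named in the text are Capn3, Ky in the genotype comparisons, the 10 largest rises and the 10 largest falls that passed in each comparison without unnamed clones, and up to 4 members of a described list with the smallest p. Where no gene passed, the 5 smallest p values are given as values. Some neighbours of Capn3 and members of other lists are named outside this rule, after their values were seen.

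Fisher's exact test compared the share of called genes within 10 Mb of Capn3 with that of all other genes with a known position, Capn3 left out. It was two-sided and adjusted over 4 genotype comparisons.

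The gene calls by limma in each comparison were tested on simulated data with the group sizes of these arrays. Each probe set was given 1 mean and 1 spread, the spread pooled over all 8 groups and so over both muscles. The simulated shares for quadriceps and soleus thus do not reflect the separate spread of each muscle. Simulated values varied independently between genes and arrays, with no batch by code and no effect shared by both muscles of a mouse. The list tests and Fisher's test were not simulated. Shares in the real arrays can therefore differ from those given here. The simulated share recovered at a true change of 1 log2 unit was 99% in adult quadriceps, 96.8% in adult soleus, 90.6% in young quadriceps and 91.7% in young soleus. At 0.5 log2 units it was 74% in adult quadriceps, 68.1% in adult soleus, 41.8% in young quadriceps and 41.7% in young soleus. For age, the share at 0.5 log2 units was 43.9% in wt quadriceps, 44.1% in wt soleus, 44.9% in C3KO quadriceps and 54.2% in C3KO soleus. For the difference between ages in the genotype effect it was 16.8% in quadriceps and 7.14% in soleus, and for genotype by muscle 16.3% in adults and 15.3% in young mice. False calls made up 11 of 179 calls in adult quadriceps and 6 of 134 in young soleus.

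No arrays of a group held identical values. The lowest correlation between arrays of a group was 0.925 in C3KO young soleus and at least 0.979 in the other groups. Pairing of the muscles comes from the mouse names in the labels. The deviations of both arrays of a mouse from their group means correlated with a median r of 0.16 across genes (from −0.19 to 0.39, 12 of 19 mice over 0.1), and 12 mice matched their own other muscle best.

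A numeric code in the sample descriptions was treated as a possible batch. Codes starting with 1-1 belong to adult mice Q2-1 to Q2-3, M2-1 and M2-2 and to the quadriceps of Q2-4, a code starting with 1-4 belongs only to the soleus array of young C3KO mouse H4-2, and all others start with 1-3. The code was entered as a block of 1-1 against the rest, and the adult genotype comparisons were also fitted within 1-3. Within 1-1 there is 1 wt mouse with a group, too few for a value. Alternatives also covered the filter on dim probe sets, quantile normalization, median centring, limma's trend and robust options, array weights, all probe sets in place of 1 per gene, fits of the 2 groups compared alone, the mouse name prefix as a random effect, all 8 groups with a replicate block on the mouse, and each array left out in turn. Leaving out the H4-2 soleus array, the code block in the age comparisons, and the difference between the 3' and 5' actin control probe sets of each array as a covariate were chosen after seeing the data, as were lists of liver, hindlimb position and anterior Hox genes.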

Results

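Gene expression was measured in quadriceps and soleus of 22 male mice, in 42 arrays. The mice were wild type (wt) or C3KO, read here from general knowledge as a knockout of Capn3, which encodes calpain 3, a protease of skeletal muscle. Both genotypes carry the same label for a cross of strains, one of them C57BL/6. Adult mice were 11 to 12 months old and young mice 2 to 3 months. Quadriceps is mostly fast muscle and soleus is rich in slow fibres. The groups with arrays were adult quadriceps (7 C3KO, 6 wt), adult soleus (6 C3KO, 5 wt), young quadriceps (4 C3KO, 4 wt) and young soleus (4 C3KO, 4 wt). Quadriceps and soleus arrays come largely from the same mice, so results in both muscles are not independent. All 4 wt young mice share the name prefix F4, and young C3KO mice carry the prefixes J4 and H4. No prefix is shared between groups of genotype and age. Differences that involve the wt young mice are therefore not told apart from a property of the F4 mice.

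Capn3 expression separated the genotypes on every array. Its main probe set was lower in C3KO by a log2 change of −5.87 ± 0.10 in adult quadriceps, −5.80 ± 0.15 in adult soleus, −5.81 ± 0.12 in young quadriceps and −5.97 ± 0.18 in young soleus. The adjusted p values are 2.42e-22, 1.33e-15, 6.39e-20 and 1.51e-14. As measured these are falls of 58.7-fold, 55.9-fold, 56.1-fold and 62.5-fold. They are lower bounds, because the C3KO values lie near the middle of each array, where signal is not told from background. A second Capn3 probe set gave log2 changes of −6.23, −6.50, −6.31 and −6.27. On all 21 C3KO arrays the main probe set lay between the 36.5th and 57.6th percentile of its array, and on all 21 wt arrays between the 96.3th and 97.5th. Whether either probe set lies in the deleted part of Capn3 is not known here. Capn3 did not change detectably with age in wt (log2 change −0.06 in quadriceps and 0.07 in soleus), nor between the muscles of wt adults (0.12 ± 0.13, adjusted p = 0.497). In C3KO it lay near background at both ages, so a change with age could not have shown there.

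**Figure D1:**
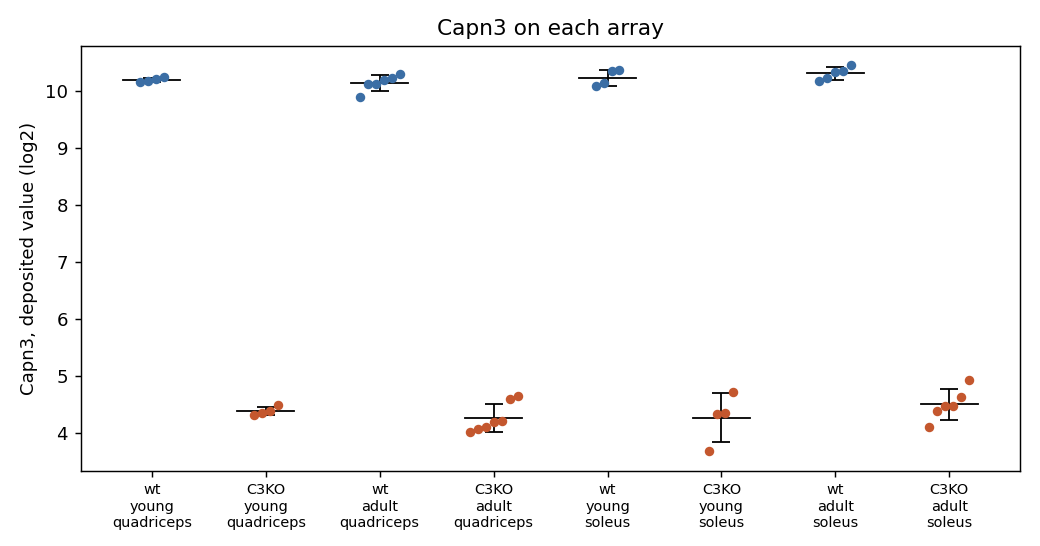
Deposited log2 values of Capn3 on each array (points) in the 8 groups of genotype, age and muscle, with the group mean (line) and SD (bars). In adult quadriceps the group means were 10.14 ± 0.14 in wt and 4.26 ± 0.25 in C3KO, and the genotypes did not overlap in any muscle or age.

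In adult quadriceps, the largest rise in C3KO was in Tmem87a (log2 change 3.11 ± 0.11, adjusted p = 7.64e-15), followed by Cap1, which encodes a regulator of actin filament turnover (2.36 ± 0.18, adjusted p = 1.72e-08). Pla2g4e, which encodes a cytosolic phospholipase, rose by 1.26 ± 0.12, Alpk3, which encodes a kinase-like protein of the sarcomere, by 1.22 ± 0.20, and Zscan29 by 1.15 ± 0.14. Spata5l1 fell by 1.91 ± 0.16, and Mga, which encodes a partner of the transcription factor Max, by 1.20 ± 0.11. Golm2 fell by 1.13 ± 0.15, Zfp593 by 0.87 ± 0.13 and Mcm8 by 0.83 ± 0.13. All 7 C3KO arrays lay beyond all 6 wt arrays for each of these genes. Cap1 in wt (mean 3.94, 5 of 6 arrays) and Golm2 in C3KO (4.58, 1 of 7) lay at or under the array median, so their changes are lower bounds. Spata5l1 (2.60, 7 of 7) and Mcm8 (3.81, 7 of 7) in C3KO did so too. The wt mean of Spata5l1 and the wt values of Mcm8 (4.43 to 5.11) were close to the array median as well, so the sizes of these falls are open. Other genes passed more narrowly: Xirp1, which encodes an actin-binding protein of remodelling muscle (1.40 ± 0.30, adjusted p = 0.0271), Rcan1, which encodes a calcineurin inhibitor (1.13 ± 0.25, adjusted p = 0.0291), and Tnfrsf12a, which encodes the TWEAK receptor (1.13 ± 0.23, adjusted p = 0.0153). Pfkfb3, a regulator of glycolysis, fell by 1.37 ± 0.30 (adjusted p = 0.0271). Ky, a gene whose loss causes myopathy in mice, had a change of −0.54 ± 0.16 that did not pass (adjusted p = 0.158).

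In total 82 of 11915 genes passed in adult quadriceps, 36 higher and 46 lower in C3KO, 20 of them by more than 2-fold. The count was 49 without the array of Q2-1, 137 without U2-3, 51 without wt X2-2 and 54 without wt X2-3. It was 56 with the code as a block and 24 within code 1-3. A sign of RNA quality, the difference between the 3' and 5' actin probe sets, moved with genotype here: it was 0.157 ± 0.0534 (SD) in wt and 0.272 ± 0.0716 in C3KO. With it as a covariate 69 genes passed, of which 51 were among the 82, and the calls of Pisd-ps3, Lmod2, Hddc3 and Sfpq were lost (adjusted p between 0.0604 and 0.0916). Of 19 named genes besides Capn3, 11 passed in every fit with 1 array left out. The calls of Xirp1, Rcan1, Pfkfb3, Pisd-ps3, Lmod2, Hddc3 and Cpeb2 were each lost in 6 to 10 of the 13 such fits, and that of Sfpq without M2-2 (adjusted p = 0.0504). With the code as a block the calls of Xirp1 (1.10, adjusted p = 0.136), Rcan1 (0.83, adjusted p = 0.141), Pfkfb3 (−0.90, adjusted p = 0.0803), Tnfrsf12a (1.00, adjusted p = 0.0774), Lmod2, Hddc3 and Cpeb2 were lost. Within code 1-3 so were those of Alpk3 (1.13, adjusted p = 0.0864), Mcm8 (−0.86, adjusted p = 0.0651) and Pisd-ps3.

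Among the lists, slow fibre genes had a median change of 1.28 in adult C3KO quadriceps (camera adjusted p = 4.51e-04, adjusted p = 0.635 with an estimated correlation). None of the 12 measured members passed alone in limma, 0 also when adjusted over the list alone: Tnnt1 had 1.78 ± 0.79 and Tpm3 1.55 ± 0.69. The mean of the slow genes ran from 5.34 to 8.17 over the 6 wt arrays and from 5.93 to 8.89 over the 7 C3KO arrays. Genes of fatty acid use had a median of 0.16 with 0 of 22 passing, 0 also adjusted over the list alone (camera adjusted p = 0.00272, adjusted p = 0.637 with an estimated correlation), with Pdk4 at 0.77 ± 0.26 and Lpl at 0.39 ± 0.15. Lpl is also high in fat, and adipocyte genes had a median of the same sign, 0.45, with 0 of 8 passing, 0 also adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.635 with an estimated correlation). Their mean was 7.30 ± 0.29 (SD) in wt and 7.66 ± 0.40 in C3KO arrays, so a difference in fat content is not told apart from one in fatty acid use. Genes of excitation-contraction coupling had a median of −0.12, 0 of 18 passing and 4 lower when adjusted over the list alone, among them Cacng1 at −0.38 ± 0.10 (camera adjusted p = 0.00633, adjusted p = 0.635 with an estimated correlation). With the actin covariate their median was −0.08, with 1 lower adjusted over the list alone (camera adjusted p = 0.0182). Interferon and MHC class I genes had a median of −0.14, 0 of 16 passing and 2 lower when adjusted over the list alone, Usp18 (−0.53 ± 0.14) and H2-K1 (−0.37 ± 0.11) having the smallest p (camera adjusted p = 0.00854, adjusted p = 0.635 with an estimated correlation). In these 5 lists with no member passing, the background is 1289 genes at an unadjusted p under 0.05 by limma.

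In adult soleus, Tmem87a (2.41 ± 0.21, adjusted p = 2.98e-06) and Cap1 (2.33 ± 0.22, adjusted p = 7.11e-06) again had the largest rises in C3KO. Alpk3 rose by 1.84 ± 0.26, Acer2, which encodes an alkaline ceramidase, by 1.38 ± 0.18, Pla2g4e by 1.20 ± 0.18, Fibin by 1.20 ± 0.18 and Alad, an enzyme of haem synthesis, by 1.07 ± 0.11. Adal fell by 0.61 ± 0.09. All 6 C3KO arrays lay beyond all 5 wt arrays for each of these genes. Cap1 in wt (mean 4.07) lay at or under the array median on 3 of 5 arrays, so its rise is a lower bound. Ky fell by 1.46 ± 0.29 with an adjusted p of 0.0495, beyond all wt arrays in 5 of 6 C3KO arrays. That call was lost in 9 of the 11 fits with 1 array left out (adjusted p up to 0.141) and with the code as a block (−1.24, adjusted p = 0.123). Bdnf, which encodes a neurotrophin, rose by at least 1.04 ± 0.20 from a wt mean near background (4.00), and its call was also lost in 9 of 11 and with the code as a block.

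In total 20 of 11969 genes passed in adult soleus, 14 higher and 6 lower in C3KO, and 11 changed by more than 2-fold. The count was 74 without the array of wt M2-2, 14 with the code as a block and 6 within code 1-3. There the calls of Alpk3 (1.25, adjusted p = 0.105), Pla2g4e (0.90, adjusted p = 0.0927), Fibin (1.35, adjusted p = 0.0557) and Adal (−0.60, adjusted p = 0.151) were lost. Atrophy and autophagy genes had a median of 0.17, with 0 of 16 passing and 3 higher when adjusted over the list alone (camera adjusted p = 0.00144, adjusted p = 0.455 with an estimated correlation). Their smallest p values belonged to Foxo1, a regulator of atrophy genes (0.67 ± 0.14, adjusted p = 0.0597), and Ddit4, an inhibitor of mTOR signalling (1.33 ± 0.30, adjusted p = 0.0974). Interferon and MHC class I genes had a median of −0.32, with 0 of 16 passing and 0 adjusted over the list alone (camera adjusted p = 5.67e-07, adjusted p = 0.910 with an estimated correlation). By limma 984 genes had an unadjusted p under 0.05.

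In young quadriceps, Tmem87a rose by 3.40 ± 0.15 (adjusted p = 1.92e-13) in C3KO. Sdc4, which encodes the cell surface proteoglycan syndecan 4, rose by 2.92 ± 0.30 (adjusted p = 3.93e-06), Pisd-ps3 by 2.78 ± 0.44, Vegfc, a lymphatic growth factor, by 2.73 ± 0.33 (adjusted p = 5.81e-05) and Cap1 by 1.84 ± 0.23. Hspa1b, an inducible heat shock protein gene, fell by 3.19 ± 0.61 (adjusted p = 0.0104), Spata5l1 by 2.08 ± 0.21, Smox, which encodes spermine oxidase, by 1.81 ± 0.32, Icam1, a leukocyte adhesion molecule, by 1.44 ± 0.21 and Serinc3 by 1.43 ± 0.17. All 4 C3KO arrays lay beyond all 4 wt arrays for each of these genes. Cap1 in wt (mean 4.18) and Icam1 in C3KO (3.83) lay at or under the array median on all 4 arrays, and Vegfc in wt (4.46) on 1, so these changes are lower bounds. Spata5l1 in C3KO (2.61) did so on all 4 arrays too, but its value in wt F4-1 (3.84) also lay under the median, so the size of its fall is open. Ky had a change of 0.03 ± 0.21 (adjusted p = 0.978), and this estimate took the other sign without J4-1, H4-1 or F4-1.

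In total 108 of 11915 genes passed in young quadriceps, 42 higher and 66 lower, and 26 changed by more than 2-fold. The count was 48 without J4-1, 70 without J4-2, 71 without H4-2, 69 without wt F4-1 and 49 without wt F4-2. Calls of Hspa1a, Dnajb1, Nr4a3 and Sh3rf2 were each lost in 6 of the 8 fits with 1 array left out, those of Socs3 without F4-1 or F4-2 and of Mss51 without F4-2 (adjusted p = 0.0533). Hspa1b did not pass when the 2 groups were fitted alone (adjusted p = 0.0894).

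Heat shock protein genes were lower as a group in young C3KO quadriceps: 7 of 17 measured members fell, 10 did not pass, and 16 were lower when adjusted over the list alone. Besides Hspa1b, Hsph1 fell by 0.93 ± 0.15 (adjusted p = 0.00191), Hsp90aa1 by 0.87 ± 0.18 and Cryab, the small heat shock protein of the Z-disc, by 0.64 ± 0.13. Their median change was −0.61 (camera adjusted p = 1.24e-19), and this call held with an estimated correlation (adjusted p = 0.0111). Without wt F4-2 or F4-4 the count of members that fell was 3, while the list stayed below the threshold with an estimated correlation in each fit with 1 wt young array left out (adjusted p between 0.00558 and 0.0272). Immediate early genes had a median of −0.53, with Nr4a3 the 1 of 15 that fell and 4 lower when adjusted over the list alone (camera adjusted p = 1.75e-04, adjusted p = 0.664 with an estimated correlation). Without F4-1 or F4-2, among others, Nr4a3 did not pass (adjusted p up to 0.967). Interferon and MHC class I genes had a median of 0.31, with 0 of 16 passing, and 6 higher and 1 lower when adjusted over the list alone, such as Tap1 (0.37 ± 0.12), against 1328 genes at an unadjusted p under 0.05 by limma (camera adjusted p = 4.03e-04, adjusted p = 0.564 with an estimated correlation).

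**Figure D2:**
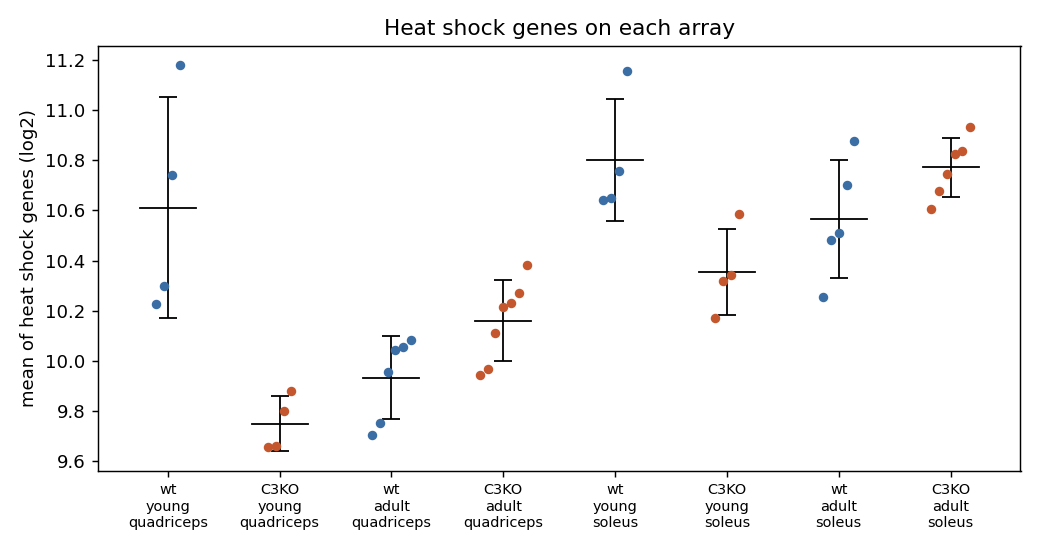
Mean deposited log2 value of the heat shock protein genes on each array (points) in the 8 groups, with the group mean and SD. The 4 wt young quadriceps arrays (10.61 ± 0.44) lay above the 4 C3KO young ones (9.75 ± 0.11), and wt adult arrays were at 9.93 ± 0.16.

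In young soleus, Sdc4 (3.27 ± 0.32, adjusted p = 8.48e-06), Tmem87a (2.81 ± 0.25, adjusted p = 3.01e-06), Vegfc (2.32 ± 0.22, adjusted p = 8.48e-06) and Cap1 (2.25 ± 0.26) had the largest rises in C3KO. Blvrb, which encodes a biliverdin reductase, rose by 1.28 ± 0.19, Rab4a, an endosomal GTPase, by 1.09 ± 0.15 and Alad by 0.98 ± 0.13. Ndrg4 fell by 2.06 ± 0.37, Cdh22, which encodes a cadherin, by 1.27 ± 0.19, Zfp593 by 1.23 ± 0.16 and Serinc3 by 1.05 ± 0.13. All 4 C3KO arrays lay beyond all 4 wt arrays for each of these genes. Cap1 (mean 4.17) and Tmem87a (4.47) in wt and Cdh22 in C3KO (4.31) lay at or under the median on 2 or 3 of 4 arrays, so their changes are lower bounds. Sdc4, Vegfc and Blvrb were also called with age in wt in both muscles, which rests on the same wt young mice. Ky had a change of 0.05 ± 0.34 (adjusted p = 0.961), of the other sign without J4-1, F4-1 or F4-2.

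The soleus array of C3KO young mouse H4-2 stood apart from all other soleus arrays in genes foreign to soleus. Its median over 18 liver genes, among them Alb and Apoa1, was 12.18 where the other arrays of the group lay between 3.82 and 4.21, and its difference between slow and fast fibre genes (−2.90) was the lowest among soleus arrays, which reached 1.03. The following young soleus results are given with and without it. In total 41 of 11969 genes passed, 12 higher and 29 lower, 22 by more than 2-fold, and 37 passed without H4-2, of which 29 were shared. The count was 103 without J4-2 and 24 without wt F4-2. The actin 3' to 5' difference was 0.367 ± 0.138 (SD) in wt and 0.193 ± 0.110 in C3KO, and with it as a covariate 53 genes passed, of which 31 were among the 41, with the calls of Cilp and Thbs4 lost (adjusted p = 0.0872 for both). Calls of Cilp, Dct, Fibin, Rgcc and Thbs4 were each lost in 6 or 7 of the 8 fits with 1 array left out, the last 3 of them also without H4-2, and that of Zfp30 in 4.

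In young soleus heat shock protein genes had a median of −0.31, with Hsph1 the 1 of 17 that fell (−0.91 ± 0.16, adjusted p = 0.00894) and 11 lower when adjusted over the list alone (camera adjusted p = 4.95e-05, adjusted p = 0.735 with an estimated correlation). Without H4-2 that median was −0.27 (camera adjusted p = 4.25e-05, adjusted p = 0.568 with an estimated correlation), with 2 lower when adjusted over the list alone. Interferon and MHC class I genes had a median of 0.38, with 0 of 16 passing and 0 adjusted over the list alone, against 1637 genes at an unadjusted p under 0.05 by limma (camera adjusted p = 1.37e-05, adjusted p = 0.735 with an estimated correlation). Without H4-2 their median was 0.10 (camera adjusted p = 0.0178, adjusted p = 0.568 with an estimated correlation). Macrophage genes had a median of −0.41 with 3 lower when adjusted over the list alone (camera adjusted p = 0.00885, adjusted p = 0.885 with an estimated correlation), and −0.70 with 12 lower without H4-2 (camera adjusted p = 3.95e-12, adjusted p = 0.555 with an estimated correlation). Tendon genes, with Thbs4 the 1 of 8 that fell (−1.07 ± 0.23) and 2 lower when adjusted over the list alone, had a camera adjusted p of 0.0388 (adjusted p = 0.735 with an estimated correlation) that was lost without H4-2. The calls of the tendon and macrophage lists were lost with the actin 3' to 5' difference of each array, a sign of RNA quality, as a covariate (camera adjusted p = 0.171 and 0.252). That fit keeps H4-2, and the covariate was not tried without it.

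Genes called between the genotypes clustered around Capn3 on chromosome 2 in both muscles at both ages. Within 10 Mb of Capn3, 19 of 130 tested genes (14.6%) were called in adult quadriceps, against 62 of 11768 others (0.527%), an odds ratio of 32.3 (95% interval 17.6 to 56.8, Fisher's exact test, adjusted p = 4.77e-20). In adult soleus 6 of 132 were called against 13 of 11818 (odds ratio 43.2, adjusted p = 5.21e-08 by the exact test), in young quadriceps 12 of 130 against 95 of 11768 (12.5, adjusted p = 3.56e-09) and in young soleus 6 of 132 against 34 of 11818 (16.5, adjusted p = 4.57e-06). Tmem87a, Pla2g4e, Zscan29, Spata5l1, Mga and Golm2 lie within this distance, as do Exd1 (0.90 ± 0.09 in adult quadriceps) and Haus2 (−0.77 ± 0.11), chosen here after their values were seen. Of the 19 neighbours called in adult quadriceps, 8 were higher and 11 lower in C3KO, 16 were still called with the code as a block and 9 within code 1-3, while of the 62 others 32 and 11 were. All 19 had the same sign in young quadriceps, whose arrays come from other mice, where 37 of the 62 other genes did (two-sided binomial p = 0.162).

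**Figure D3:**
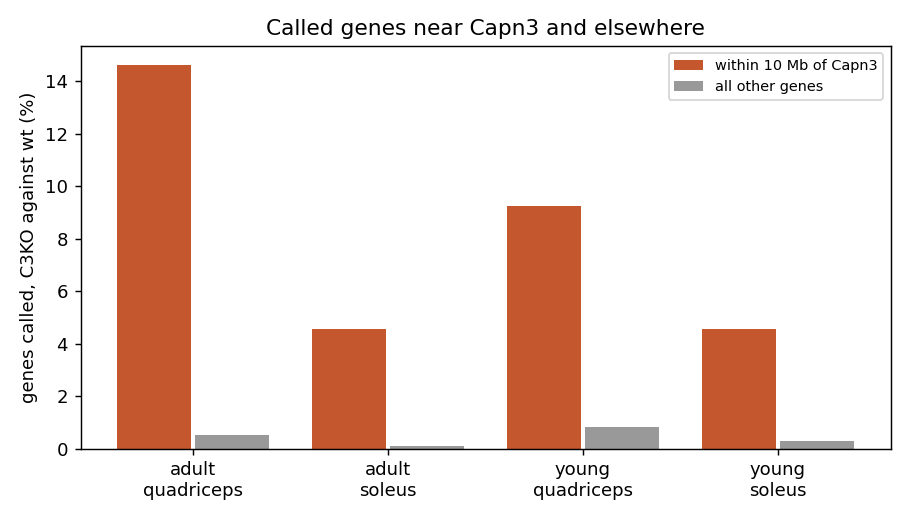
Percentage of tested genes called at an adjusted p under 0.05 within 10 Mb of Capn3 and among all other genes, in the 4 genotype comparisons, with Capn3 itself left out. In adult quadriceps these shares were 14.6% and 0.527%, and in young quadriceps 9.23% and 0.807%.

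In all 4 genotype comparisons 5 genes were called, each with 1 sign: Capn3, Tmem87a (2.41 to 3.40), Pla2g4e (1.20 to 1.37) and Adal (−0.75 to −0.50) on chromosome 2, and Cap1 (1.84 to 2.36, each a lower bound) on chromosome 4. Called genes were also frequent on chromosome 4 in adults. In quadriceps 21 of its 727 tested genes were called, an odds ratio of 9.77 (5.31 to 17.7, Fisher's exact test, adjusted p = 3.74e-11) against chromosomes other than 2 and 4, and in adult soleus 6 of 740 (20.9, adjusted p = 1.51e-04 by the exact test). In young quadriceps 10 of 727 were called (1.91, adjusted p = 0.307 by the exact test) and in young soleus 4 of 740 (2.65, adjusted p = 0.333).

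**Figure D4:**
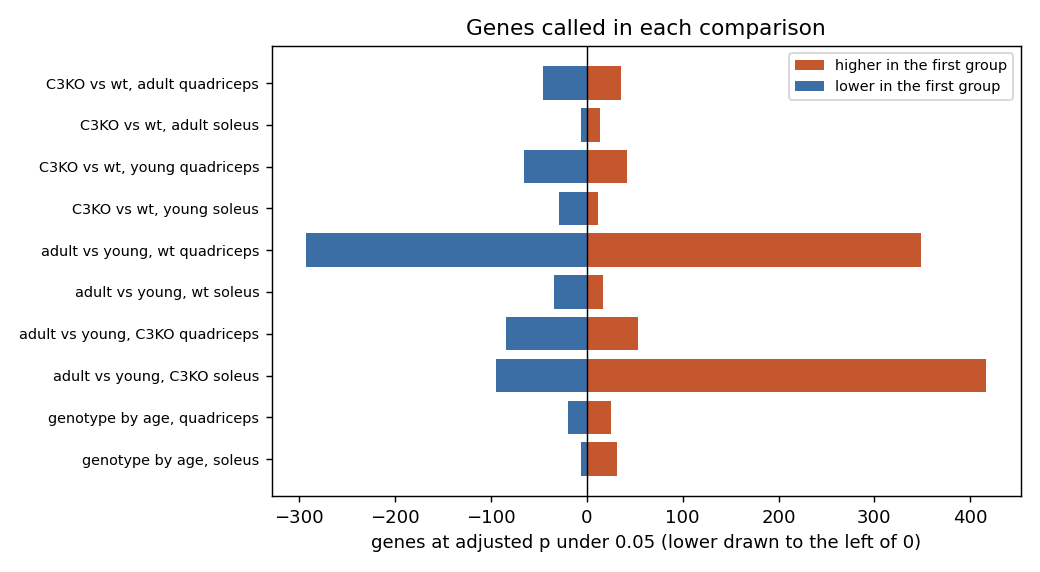
Number of genes at an adjusted p under 0.05 in 10 comparisons, with genes higher in the first group drawn to the right of 0 and lower ones to the left. The largest counts were 642 for age in wt quadriceps and 512 for age in C3KO soleus.

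From young to adult wt quadriceps, Lep, which encodes the fat hormone leptin, rose by 2.54 ± 0.51 (adjusted p = 0.00573), Dkk3, which encodes a secreted Wnt regulator, by 1.66 ± 0.25 (adjusted p = 4.71e-04), Vegfc by 2.08 ± 0.30 (adjusted p = 4.12e-04), Sdc4 by 1.50 ± 0.27 and Hddc3 by 2.69 ± 0.46. Actc1, the cardiac actin gene also used in developing muscle, fell by 1.96 ± 0.36 (adjusted p = 0.00316), Hspa1b by 2.78 ± 0.56 (adjusted p = 0.00573) and Dnajb1, an Hsp70 partner, by 1.53 ± 0.33. All 6 adult arrays lay beyond all 4 young arrays for each of these genes. Lep lay at or under the array median on 3 of 4 young arrays (mean 4.09) and Vegfc on 1 (4.46), so their rises are lower bounds. This comparison and the young genotype comparison share the 4 wt young arrays, so values of Vegfc, Sdc4 and Hspa1b in both are not independent.

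In total 642 of 11915 genes passed with age in wt quadriceps, 349 higher and 293 lower in adults, 71 by more than 2-fold. The count was 335 without F4-1, 291 without F4-4 and 618 with the code as a block. A sign of RNA quality moved with age here: the difference between the 3' and 5' actin probe sets was 0.157 ± 0.0534 (SD) in adult and 0.366 ± 0.189 in young wt quadriceps, and with it as a covariate 243 genes passed. Extracellular matrix genes had a median of −0.64, with 14 of 28 lower, 14 not passing and 21 lower when adjusted over the list alone (camera adjusted p = 1.74e-19, adjusted p = 0.136 with an estimated correlation). The collagen genes Col1a1 (−1.36 ± 0.22), Col1a2 (−1.17 ± 0.19), Col5a2 (−1.05 ± 0.17) and Col4a1 (−0.90 ± 0.14) were among those that fell. With the actin covariate 9 of the 28 fell and 15 when adjusted over the list alone, with a median of −0.51 (camera adjusted p = 1.11e-15, adjusted p = 0.190 with an estimated correlation). Heat shock protein genes had a median of −0.41, with 9 of 17 lower and 10 adjusted over the list alone (camera adjusted p = 4.09e-08, adjusted p = 0.203 with an estimated correlation). Circadian clock genes had a positive direction, with 2 of 14 higher, Ciart (1.05 ± 0.24) and Tef (0.46 ± 0.11), and 6 when adjusted over the list alone (camera adjusted p = 0.00538, adjusted p = 0.382 with an estimated correlation). Genes of excitation-contraction coupling included 4 of 18 that rose, such as Ryr1, the calcium release channel (0.61 ± 0.15), and 5 when adjusted over the list alone (camera adjusted p = 0.0129, adjusted p = 0.575 with an estimated correlation), a list call lost with the actin covariate (camera adjusted p = 0.0582), where 1 rose. Jchain lost its call without F4-3 or F4-4 (adjusted p up to 0.0617), Nr4a3 without F4-1 or F4-2 (up to 0.625), Hspa1a without F4-4 (0.0605), Hmga2-ps1 without F4-1 (0.0510) and Ddit4 in 8 of the 10 fits with 1 array left out. Jchain (adjusted p = 0.0791), Ddit4 (0.0677) and Hmga2-ps1 (0.0602) also lost it with the actin covariate. Jchain lay under the array median on all 4 young arrays.

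In wt soleus, Postn, which encodes the matrix protein periostin, fell with age by 2.38 ± 0.30 (adjusted p = 5.90e-04) and Alpk3 by 2.07 ± 0.29 (adjusted p = 0.00174). Sdc4 rose by 2.14 ± 0.30 (adjusted p = 0.00174), Vegfc by 1.92 ± 0.21 (adjusted p = 2.91e-04) and Rab4a by 1.18 ± 0.15. All 5 adult arrays lay beyond all 4 young arrays for each of these genes. In total 51 of 11969 genes passed, 17 higher and 34 lower, so that 33.3% were higher, against 44.1% after quantile normalization and 45.5% after median centring. The count was 26 without M2-2, 12 without W2-1, 13 without W2-3, 20 without X2-3, 15 without F4-1, 8 without F4-2, 14 without F4-3 and 13 without F4-4. Of the 20 named genes besides Capn3, 14 lost their call in at least 1 fit with 1 array left out. The actin difference was 0.222 ± 0.157 (SD) in adult and 0.367 ± 0.138 in young wt soleus, and with it as a covariate 20 genes passed. Extracellular matrix genes had a median of −0.57, with 4 of 28 lower and 23 when adjusted over the list alone (camera adjusted p = 6.15e-20, adjusted p = 0.197 with an estimated correlation). Besides Postn, Col4a1 fell by 0.74 ± 0.12 (adjusted p = 0.00765), Col5a2 by 1.02 ± 0.19 and Lox, which encodes a collagen cross-linking enzyme, by 1.11 ± 0.22. The last 2 lost their call in 7 of 9 fits with 1 array left out and with the actin covariate, where 2 of the 28 matrix genes fell, 12 when adjusted over the list alone (camera adjusted p = 5.91e-13, adjusted p = 0.339 with an estimated correlation). Atrophy and autophagy genes had Foxo1 as the 1 of 16 that fell (−0.75 ± 0.16), with 1 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.00239, adjusted p = 0.268 with an estimated correlation).

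In C3KO quadriceps, collagen genes again fell with age: Col1a1 by 1.52 ± 0.22 (adjusted p = 7.45e-04), Col3a1 by 1.39 ± 0.20 and Col1a2 by 1.35 ± 0.18 (adjusted p = 5.68e-04). Dkk3 rose by 1.68 ± 0.24 (adjusted p = 7.45e-04) and Amy1, an amylase gene, by 1.04 ± 0.13, and Sytl2 fell by 1.11 ± 0.13. All 7 adult arrays lay beyond all 4 young arrays for each of these genes. Actc1 fell by 1.96 ± 0.35 (adjusted p = 0.00844), and its call was lost without J4-1 or J4-2 (adjusted p up to 0.0559) and with the code as a block (−1.95, adjusted p = 0.0645). Matrix genes had a median of −0.48, with 8 of 28 lower and 20 adjusted over the list alone (camera adjusted p = 3.02e-22, adjusted p = 0.0819 with an estimated correlation). Markers of cells that make matrix had negative medians too. The list of fibroblasts and fibro-adipogenic progenitors had a median of −0.31, with 0 of 9 passing and 1 lower adjusted over the list alone (camera adjusted p = 8.70e-05, adjusted p = 0.334 with an estimated correlation). Tendon genes had a median of −0.49, with 0 of 8 passing and 4 lower adjusted over the list alone (camera adjusted p = 8.70e-05, adjusted p = 0.303 with an estimated correlation). Genes of fatty acid use had a median of 0.35 with 0 of 22 passing, 0 also adjusted over the list alone, against 1376 genes at an unadjusted p under 0.05 by limma (camera adjusted p = 5.45e-07, adjusted p = 0.427 with an estimated correlation). In the adipocyte list Cidec, a lipid droplet gene, was the 1 of 8 that rose (1.67 ± 0.41, adjusted p = 0.0454), with 3 adjusted over the list alone (camera adjusted p = 2.24e-04, adjusted p = 0.303 with an estimated correlation), and its call was lost in 9 of 11 fits with 1 array left out and with the code as a block (adjusted p = 0.208). Interferon and MHC class I genes had Rtp4 as the 1 of 16 that fell (−0.66 ± 0.15), with 7 adjusted over the list alone (camera adjusted p = 1.35e-05, adjusted p = 0.303 with an estimated correlation). In total 137 genes passed, 53 higher and 84 lower, and 80 without Q2-1, 79 without Q2-3, 33 without J4-1, 37 without J4-2 and 57 without H4-2. With the code as a block, which rests on arrays of code 1-3 because all young mice carry it, 18 passed.

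In C3KO soleus, Myh3, the embryonic myosin heavy chain gene, rose with age by 2.77 ± 0.55 (adjusted p = 0.0118), Ndrg4 by 2.40 ± 0.34 (adjusted p = 0.00169), Amph by 2.40 ± 0.37, Xirp1 by 1.94 ± 0.38 and Prkd1, a kinase gene, by 1.81 ± 0.24. Frzb, a secreted Wnt antagonist, fell by 1.31 ± 0.25 and Meg3, a long noncoding RNA, by 1.19 ± 0.20. All 6 adult arrays lay beyond all 4 young arrays for each of these genes. Amph lay at or under the array median on 4 of 4 young arrays (mean 3.52), Myh3 on 1 (5.28) and Frzb on 3 of 6 adult arrays (4.47), so their changes are lower bounds. Iigp1, an interferon-induced GTPase gene, fell by 2.28 ± 0.50 (adjusted p = 0.0185, and 0.0597 without J4-1). The young group includes the H4-2 array with its high liver genes (12.18) and low difference between slow and fast fibre genes (−2.90), and without it 149 genes passed in place of 512 (417 higher and 95 lower). The calls of Tecrl, Atf3, Fam107a and Col3a1 were lost without H4-2. The count was 312 without Q2-1, 289 without Q2-2, 261 without Q2-3, 223 without Q2-4, 331 without U2-1, 217 without J4-1, 872 without J4-2 and 777 with the actin covariate. With the code as a block it was 49, with calls of Ndrg4, Amph, Prkd1 and Meg3 kept and those of Myh3 (2.62, adjusted p = 0.0619), Xirp1 (1.44, adjusted p = 0.0623), Frzb (−1.25, adjusted p = 0.0588) and Iigp1 (−2.20, adjusted p = 0.0719) lost.

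Interferon and MHC class I genes had a median of −0.57 with age in C3KO soleus, with 2 of 16 lower, Tap1 (−0.54 ± 0.13) and Psmb9 (−0.61 ± 0.17), both of antigen processing, and 14 when adjusted over the list alone (camera adjusted p = 2.91e-11, adjusted p = 0.592 with an estimated correlation). Without H4-2 the median was −0.35, with 0 of 16 passing in limma and 0 adjusted over the list alone (camera adjusted p = 2.03e-08, adjusted p = 0.397 with an estimated correlation). In the list of titin and Z-disc partners 4 of 23 rose, among them Ankrd1, a stress-responsive titin partner (1.74 ± 0.27, adjusted p = 0.00410), Myoz1 fell by 0.78 ± 0.20, and 11 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00208, adjusted p = 0.711 with an estimated correlation). That list call was lost without H4-2 (camera adjusted p = 0.0565), where 2 rose and 0 fell. Slow fibre genes included 2 of 12 that rose, Pln, a regulator of the calcium pump (1.60 ± 0.35), and Myh7b (0.96 ± 0.25), 2 also when adjusted over the list alone (camera adjusted p = 0.00130, adjusted p = 0.711 with an estimated correlation). Without H4-2, which had the lowest slow minus fast value, 0 of the 12 slow genes passed in limma (camera adjusted p = 0.0283, adjusted p = 0.508 with an estimated correlation). Heat shock protein genes included 4 of 17 that rose, such as Hspa1a (1.70 ± 0.42), and 11 adjusted over the list alone (camera adjusted p = 0.00130, adjusted p = 0.711 with an estimated correlation). Of these 17, without H4-2, 0 passed in limma and 8 adjusted over the list alone (camera adjusted p = 1.69e-04, adjusted p = 0.407 with an estimated correlation). Neuromuscular junction genes included Musk (1.14 ± 0.21, adjusted p = 0.00916) and Ncam1 (0.59 ± 0.14), 2 of 15 that rose and 3 adjusted over the list alone (camera adjusted p = 0.0190, adjusted p = 0.711 with an estimated correlation), and this list call was lost without H4-2 (camera adjusted p = 0.0609), where 1 rose. By limma 2553 genes had an unadjusted p under 0.05 with all arrays.

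The genotype effect differed between ages in quadriceps for 45 genes, 25 with a more positive effect in adults and 20 with a more negative one. Hspa1b had the largest difference (4.31 ± 0.78, adjusted p = 0.0160), followed by Hspa1a (4.04 ± 0.77, adjusted p = 0.0271) and Nr4a3 (3.93 ± 0.76, adjusted p = 0.0271). Noct, a clock-controlled gene, differed by 1.76 ± 0.28, Nudt18 by 1.54 ± 0.25, Vegfc by −2.48 ± 0.42, Pfkfb3 by −2.73 ± 0.48 and Sdc4 by −1.90 ± 0.38. For Nr4a3 (wt adult, 2 of 6 arrays) and Vegfc (wt young, 1 of 4) a group lay partly at or under the array median, so these differences are lower bounds in size. Of the 20 named genes besides Capn3, Noct, Nudt18, Pfkfb3 and Vegfc passed in every fit with 1 array left out, while Hspa1b was lost without J4-1 (adjusted p = 0.0539), Hspa1a without X2-2, J4-1 or F4-4 and Sdc4 without X2-2, J4-1, J4-2, F4-2 or F4-4. The heat shock protein list had a median difference of 0.80, with 4 of 17 passing, 12 when adjusted over the list alone, among them Hsp90aa1 (1.09 ± 0.23) and Hspb6 (0.82 ± 0.17). This list call (camera adjusted p = 2.70e-15) held with an estimated correlation (adjusted p = 0.0351). The count of 45 was 28 without W2-1, 10 without X2-2, 27 without Q2-3, 28 without Q2-4, 75 without U2-3, 9 without J4-1, 19 without J4-2, 27 without H4-1, 21 without F4-1, 20 without F4-2, 68 without F4-3 and 15 without F4-4. It was 18 with the code as a block, where Hspa1a (3.76, adjusted p = 0.0509), Nr4a3 (3.66, adjusted p = 0.0509) and Sdc4 (−1.83, adjusted p = 0.0537) did not pass.

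In soleus the genotype effect differed between ages for 38 genes, 32 more positive and 6 more negative in adults. Vegfc differed by −2.62 ± 0.30 (adjusted p = 3.79e-04), Sdc4 by −2.35 ± 0.42 (adjusted p = 0.0198), Ndrg4 by 3.13 ± 0.49 (adjusted p = 0.00786), Alpk3 by 2.78 ± 0.40 (adjusted p = 0.00647) and Acer2 by 1.83 ± 0.27. Vegfc, Ndrg4, Alpk3, Acer2, Rgcc and Dct passed in every fit with 1 array left out, and Sdc4 did not without F4-1 (adjusted p = 0.0595). In the atrophy and autophagy list 2 of 16 passed, Foxo1 (1.44 ± 0.22, adjusted p = 0.00781) and Ddit4 (2.17 ± 0.46), and 3 when adjusted over the list alone (camera adjusted p = 0.00100, adjusted p = 0.336 with an estimated correlation, and 0.264 without H4-2, where 1 passed). The call of Ddit4 was lost in 16 of 19 fits with 1 array left out and with the code as a block (adjusted p = 0.0848). In the heat shock protein list 2 of 17 passed, Hsph1 (1.16 ± 0.21) and Hspb1 (1.11 ± 0.23), and 7 adjusted over the list alone (camera adjusted p = 1.40e-05, adjusted p = 0.428 with an estimated correlation, and 0.342 without H4-2, where 1 passed). Without the H4-2 array 32 genes passed, of which 23 were among the 38. The count was 148 without M2-2, 16 without W2-1, 14 without W2-3, 19 without X2-2, 16 without X2-3, 13 without Q2-2, Q2-3 or Q2-4, 100 without J4-2, 18 without H4-1, 15 without F4-1, 12 without F4-2, 19 without F4-3 and 20 without F4-4. With the code as a block it was 17 and with the actin covariate 70.

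Soleus and quadriceps of wt adult mice differed in 4974 of 12256 genes within 5 mice, 2296 higher and 2678 lower in soleus. The slow fibre genes Myh7 (7.02 ± 0.60, adjusted p = 1.15e-08), Tnni1 (6.59 ± 0.53), Tnnt1 (6.51 ± 0.57) and Atp2a2, the slow calcium pump (4.79 ± 0.29), were higher in soleus, and 11 of 12 members passed, as they did adjusted over the list alone (camera adjusted p = 1.42e-11, adjusted p = 0.311 with an estimated correlation). Fast fibre genes were lower in 12 of 13, also adjusted over the list alone, with Pvalb, a calcium buffer of fast fibres, at −3.30 ± 0.47 and Actn3, the fast fibre alpha-actinin, at −3.81 ± 0.65 (camera adjusted p = 4.13e-06, adjusted p = 0.311 with an estimated correlation). Genes of fatty acid use rose in 20 of 22, such as Lpl (1.22 ± 0.12), also adjusted over the list alone (camera adjusted p = 4.32e-13, adjusted p = 0.311 with an estimated correlation). Of 16 glycolysis and glycogen genes 13 were lower, among them Phkg1 (−2.51 ± 0.14) and Ldha (−1.21 ± 0.09), and 3 higher, as they were adjusted over the list alone (camera adjusted p = 2.91e-06, adjusted p = 0.363 with an estimated correlation). Tspan8 (−5.29 ± 0.37), Mybph (−5.02 ± 0.31) and Dkk3 (−4.69 ± 0.23) had the largest falls. In soleus these 3 lay at or under the median on 3 or 4 of 5 arrays, and Myh7 in quadriceps was 3.80 on the array of M2-2, so their differences are lower bounds. All 20 named genes passed in every fit with 1 mouse left out.

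The genotype effect did not differ detectably between the muscles of adult mice: 0 of 12256 genes passed in limma, and 770 had an unadjusted p under 0.05. The smallest p values belonged to Dennd2c (0.90 ± 0.18) and Nmb (−1.06 ± 0.22), both with an adjusted p of 0.501. Dennd2c lay near background in adult soleus of both genotypes (means 4.25 in wt and 4.23 in C3KO), so the size of its difference is open. Efl1 (0.51 ± 0.11), Cpeb2 (0.92 ± 0.20) and Acer2 (0.59 ± 0.13) followed, each at 0.539. Slow fibre genes had a median difference of −1.17 (camera adjusted p = 7.17e-06, adjusted p = 0.624 with an estimated correlation). In young mice Cdh22 passed alone, with an effect more negative in soleus (−1.41 ± 0.20, a lower bound in size, adjusted p = 0.00831), and 803 genes had an unadjusted p under 0.05. Its call was lost without J4-1 (adjusted p = 0.0682), where 0 genes passed in limma, and 2 passed without J4-2, F4-3 or H4-2. For heat shock protein genes the median difference in young mice was 0.31, with 0 of 17 passing and 5 adjusted over the list alone (camera adjusted p = 1.77e-08, adjusted p = 0.145 with an estimated correlation, and 0.176 without H4-2).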

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

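The tests of inherited strain DNA, of a response wherever genes lie, of shared handling of the wt young mice, of liver RNA, of liver or quadriceps RNA added to soleus and of RNA degradation were chosen only after the results were seen, whereas the splits of arrays, the code, the role of 1 wt young mouse, the genotype-dependent change with age and the muscle from outside the hindlimb were set down before their values were.

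Genes called between the genotypes concentrate near Capn3, with an odds ratio of 32.3 in adult quadriceps. DNA of another strain inherited together with the Capn3 mutation may account for this: in young quadriceps, from other mice, the odds ratio was 12.5. It stays open, because no genotypes of the mice were examined. A response of muscle to the loss of calpain 3 wherever the genes lie is argued against as the source of the cluster by the lower 95% bound of that odds ratio in young quadriceps, 6.07, although single neighbours such as Pla2g4e could respond to it. A batch that follows the code is argued against by 16 neighbours still called with the code as a block. Values measured on neighbours such as Tmem87a may also reflect sequence differences under the probes, which were not tested.

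Heat shock protein genes were higher in wt young quadriceps than the average of the other 3 quadriceps groups in 17 of 17 genes, with a median difference of 0.39. Against C3KO young alone, a single wt young mouse as the source is argued against. The camera adjusted p of that comparison was at most 2.42e-16 with each wt young array left out, and at most 0.0272 with an estimated correlation. Against the adult groups this was not tested. The array means of F4-1 (10.30) and F4-3 (10.23) lay within the C3KO adult range (9.95 to 10.38), and those of F4-2 (11.18) and F4-4 (10.74) above it. A property of the 4 wt young mice as a group, such as handling or origin, may contribute. In soleus their median shift against the average of the other 3 groups was 0.19 without H4-2, with 14 of 17 genes higher. With H4-2 kept, the soleus means of these genes were 10.80 in wt young, 10.77 in C3KO adult, 10.57 in wt adult and 10.36 in C3KO young arrays. A low C3KO young group is thus not told apart from a high wt young one in soleus. A genotype-dependent change with age cannot be told apart from a property of the wt young mice, since they carry 1 name prefix, which no other mice share. Both stay open.

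The soleus array of young C3KO mouse H4-2 stood apart in liver genes, which were higher than in the other 3 arrays of the group by a median of 7.77, in 18 of 18 genes. Liver RNA in that array is a possible source. Genes of hindlimb position had a median of −1.31 over the 7 above the array median and were lower in all 10. That median does not settle whether liver or quadriceps RNA was added to soleus RNA, because slow fibre genes were lower as well. Their mean was 10.13, where the other 3 arrays of the group lay between 11.45 and 11.77. Among the 7, Hoxc10 (2.94 against a mean of 8.78) and Hoxa9 (2.51 against 7.61) fell far more than the slow fibre genes. Dilution to the extent seen in the slow fibre genes would not lower these that far. The rest of the 7 fell by 0.34 to 1.73. RNA degradation is argued against by a 3' to 5' Gapdh difference of −0.0343, where other arrays lay between −0.0793 and 0.520. A muscle from outside the hindlimb stays open, with anterior Hox genes at a median of 0.34 (8 of 10 higher), and 0.31 over the 6 above the array median (4 higher and 2 lower). No group of the design offers a biological explanation for this array.

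Splits of the same arrays into other groups of equal size show how many calls other groupings give. A real difference between groups adds to the spread within such splits, which can lower their counts. In adult quadriceps 2 of 100 splits, the real one included, had at least the real count of 82, the highest other giving 88, and in adult soleus 1 of 100 did, with 20 real and 8 at most otherwise. In young mice 1 of 35 did in quadriceps (108 real, 1 at most otherwise) and 1 of 35 in soleus (41 and 1). For age it was 1 of 100 each time: 642 real and 128 at most otherwise in wt quadriceps, 51 and 4 in wt soleus, 137 and 16 in C3KO quadriceps, 512 and 5 in C3KO soleus. In each of these, under 1 in 20 splits had at least the real count, the real one included. For genotype, Capn3 and its neighbours, of which 6 were called in adult soleus, add to the real count in advance. No name prefix is shared between groups of genotype and age, so differences between such sets of mice are not excluded. For the difference between ages in the genotype effect 2 of 100 splits reached the real count in quadriceps (45 real, 45 in the highest other). In soleus 2 of 100 did (38 real, 51 in the highest other). Genotype labels were mixed within each age, which removes the genotype effect at both ages and not only its difference between them. These splits therefore do not decide whether chance alone gives that difference. The highest other split kept all code 1-1 arrays of adult mice on one side in quadriceps and largely followed code 1-1 in soleus. Both also largely followed genotype. In quadriceps it joined wt M2-2 to all adult C3KO mice but U2-1, and exchanged the genotypes of all young mice. In soleus it kept all young genotypes and grouped Q2-1 to Q2-4 with wt M2-2 and W2-3. Code and genotype are thus not told apart in these splits. With the code as a block the real counts were 18 and 17. For soleus against quadriceps, 16 splits were too few to decide (4974 real, 1325 at most otherwise). Chance is not excluded for genotype by muscle in young mice, where 2 of 35 splits reached the real count of 1 and the highest other gave 1. In adults the real count was 0, which all 100 splits reach whatever the data, so the splits (highest 1) decide nothing there.

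Single arrays far from the rest of their group were found in 17 of 345 groups of values, where chance gives about 1 in 20. In C3KO adult quadriceps, Rcan1 was 8.30 in U2-3 (others 9.55 to 9.91) and Stk26 6.19 in U2-2 (7.10 to 7.40). In wt adult quadriceps, Rcan1 was 9.41 in M2-2 (7.98 to 8.47), Tnfrsf12a 8.38 in W2-1 (7.51 to 7.75) and Mcm8 5.11 in X2-3 (4.43 to 4.68). In wt adult soleus, Alpk3 was 10.39 in X2-2 (9.62 to 9.84), Tmem69 6.76 in X2-2 (6.57 to 6.61) and Postn 7.84 in X2-3 (7.12 to 7.25). In C3KO adult soleus, Tecrl was 7.29 in U2-2 (8.82 to 9.30). In young quadriceps, Spata5l1 was 3.84 in wt F4-1 (others at least 4.95) and Socs3 6.08 in C3KO H4-1 (5.46 to 5.56). In young soleus, Rab4a was 6.42 in wt F4-3 (6.00 to 6.05), Cdh22 6.18 in wt F4-1 (5.35 to 5.42), Serinc3 9.24 in C3KO H4-2 (9.03 to 9.06) and the median of liver genes 12.18 in H4-2 (3.82 to 4.21). The 3' to 5' difference of X2-2 soleus was 0.314 for Gapdh (−0.0394 to 0.0114) and 0.497 for actin (0.123 to 0.197).

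Differences between ages in the genotype effect on quadriceps, by a test of the difference, were 4.31 for Hspa1b, 4.04 for Hspa1a, 3.93 for Nr4a3, 1.76 for Noct, 1.54 for Nudt18, 1.39 for Pkp4, 1.24 for Icam1, 1.21 for Ctla2a, 1.18 for Lgals3, 1.15 for Odc1, −2.73 for Pfkfb3, −2.48 for Vegfc, −1.90 for Sdc4, −1.81 for Sh3rf2, −1.44 for Sox4, −1.03 for Cd274, −1.01 for Blvrb, −0.94 for Fzd7, −0.89 for Fsd2 and −0.86 for Ap3m2. Those of Nr4a3, Vegfc and Cd274 are lower bounds in size, because groups near background would move them further from 0. That of Icam1 has an open size, because it lay near background in C3KO at both ages (means 4.21 and 3.83). On soleus they were 3.13 for Ndrg4, 2.78 for Alpk3, 2.17 for Ddit4, 1.90 for Dct, 1.83 for Acer2, 1.79 for Lgals3, 1.72 for Slc2a1, 1.71 for Rgcc, 1.62 for Tubb6, 1.58 for Lox, −2.62 for Vegfc, −2.35 for Sdc4, −1.38 for Sox4, −1.34 for Blvrb and −0.87 for Tbc1d4, with that of Dct a lower bound. Between the muscles of young mice the genotype effect on Cdh22 differed by −1.41, a lower bound in size, by the same kind of test.

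Outside every comparison, the arrays of M2-1 had values of slow minus fast fibre genes of −7.26 for the one titled soleus, where labelled soleus arrays lay between −2.90 and 1.03, and 0.18 for the one titled quadriceps, where labelled quadriceps arrays lay between −8.34 and −4.69.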

How the results depend on the processing

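Leaving out the H4-2 soleus array, and entering the code as a block in the age comparisons, were chosen only after results were seen, as was the actin covariate. Over alternatives other than leaving out 1 array, called or named genes kept their side of the threshold in 2036 fits, were no longer past it in 279 and changed sign in 5. With 1 array left out these counts were 1876, 622 and 8. Capn3 kept its fall in each genotype comparison. The code block ended 55 named calls in the age and genotype by age comparisons, and fits of the 2 groups alone ended 44 over all comparisons. The cause of these changes was not tested unless the alternative tests fewer arrays or other probe sets. The number of arrays limits what can be called, and no measure of depth applies to arrays.

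Counts that moved by over 1.5 times are given by alternative. With array weights they were 167 in adult quadriceps, 176 in adult soleus, 271 in young quadriceps and 96 in young soleus for genotype, 463 in wt soleus, 557 in C3KO quadriceps and 334 in C3KO soleus for age, and 108 in quadriceps and 163 in soleus for genotype by age. Counting all probe sets gave 132, 41, 203 and 81 for genotype in the same order, 1243 in wt and 239 in C3KO quadriceps for age, 76 for genotype by age in quadriceps and 9088 for soleus against quadriceps. Fits of the 2 groups alone, with fewer arrays, gave 52 in adult quadriceps and 23 in young soleus for genotype, and 422 in wt quadriceps and 102 in C3KO soleus for age. The mouse name prefix as a random effect gave 34 in adult and 96 in young soleus for genotype, and 89 in wt and 799 in C3KO soleus for age. All 8 groups with a replicate block on the mouse gave 84 in adult and 149 in young soleus for genotype, 141 in wt and 1135 in C3KO soleus for age, and 241 for genotype by age in soleus. Within code 1-3 the genotype counts were 24 in adult quadriceps and 6 in adult soleus. The code as a block gave 18 in C3KO quadriceps and 49 in C3KO soleus for age, and 18 in quadriceps and 17 in soleus for genotype by age. Without the H4-2 soleus array 149 passed for age in C3KO soleus and 2 for genotype by muscle in young mice. Without a filter 19 passed for age in wt soleus and 17 for genotype by age in soleus. A filter at the 75th percentile gave 73 for genotype by age in soleus and 0 in limma for genotype by muscle in young mice. Median centring gave 22 for age in wt soleus, and 28 in quadriceps and 24 in soleus for genotype by age, where quantile normalization gave 72 in quadriceps. The actin 3' to 5' difference as a covariate gave 243 in wt quadriceps, 20 in wt soleus and 777 in C3KO soleus for age, and 70 for genotype by age in soleus.

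The replicate block on the mouse as a random effect left the counts within 1.5 times for soleus against quadriceps (5283) and for genotype by muscle (0 by limma in adults, 1 in young mice), and changed the call of no named gene there, though 4755 of the 4974 genes stayed called. Of calls of lists, 162 were kept and 225 were no longer past the threshold, mostly with an estimated correlation.

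With 1 array left out, counts for genotype ran from 49 to 137 in adult quadriceps, 14 to 74 in adult soleus, 48 to 130 in young quadriceps and 24 to 103 in young soleus. For age they ran from 291 to 711 in wt quadriceps, 8 to 45 in wt soleus, 33 to 191 in C3KO quadriceps and 149 to 872 in C3KO soleus. Genotype by age gave 9 to 75 in quadriceps and 12 to 148 in soleus, soleus against quadriceps 4084 to 4832, and genotype by muscle 0 to 0 in adults and 0 to 2 in young mice. Capn3 ran from −5.94 to −5.83 in adult quadriceps, −5.89 to −5.73 in adult soleus, −5.85 to −5.79 in young quadriceps and −6.11 to −5.77 in young soleus. Changes that took the other sign, none past the threshold either way, were Capn3 for age in wt soleus with the actin covariate (−0.0719), Ky in young quadriceps without J4-1 (−0.0191), H4-1 (−0.0316, the range over arrays reaching 0.13) or F4-1 (−0.0185), Ky in young soleus without J4-1 (−0.18, the range reaching 0.23), F4-1 (−0.0211) or F4-2 (−0.0841), Capn3 for genotype by age in soleus with array weights (−0.0119) or without H4-2 (−0.0365, the range reaching 0.31), and Capn3 for genotype by muscle in young mice with array weights (0.0149) or without H4-2 (0.0776, the range starting at −0.31). The differences of Capn3 rest on C3KO values near background.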

Other observations

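The test of chromosome 4 was chosen only after its called genes were seen. In adult C3KO quadriceps, immediate early genes had a median of 0.20, with 0 of 15 passing and 2 higher when adjusted over the list alone, Atf3 (1.42 ± 0.38) and Nr4a3 (at least 1.47 ± 0.47) having the smallest p (camera adjusted p = 0.00641, adjusted p = 0.635 with an estimated correlation). By limma 1289 genes had an unadjusted p under 0.05. With the actin 3' to 5' difference as a covariate 2 of these 15 passed, both higher.

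With age in wt quadriceps, tendon genes included Tnmd (−0.87 ± 0.23) as the 1 of 8 that fell, with 7 lower when adjusted over the list alone (camera adjusted p = 8.02e-05, adjusted p = 0.382 with an estimated correlation), and endothelial genes included Flt1, a VEGF receptor (−1.08 ± 0.15), as the 1 of 11 that fell, with 3 adjusted over the list alone (camera adjusted p = 0.00538, adjusted p = 0.564 with an estimated correlation). With age in C3KO quadriceps, Chodl in the satellite cell list was the 1 of 6 that fell (−0.54 ± 0.11), with 2 adjusted over the list alone (camera adjusted p = 0.0265, adjusted p = 0.287 with an estimated correlation). Soleus of wt adults was lower than quadriceps in 17 of 19 macrophage genes, such as Cd163 (−1.21 ± 0.18), with 18 adjusted over the list alone (camera adjusted p = 3.85e-05, adjusted p = 0.529 with an estimated correlation), and higher in 11 of 17 genes of the citric acid cycle, such as Idh2 (2.79 ± 0.21), with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00163, adjusted p = 0.529 with an estimated correlation).

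A second inherited segment may lie on chromosome 4, where Cap1 lies. The odds ratio of 9.77 in adult quadriceps is what raised this hypothesis and does not test it. The called genes there span 79.4 Mb, with 16.2 Mb between their quartiles. In young quadriceps, from other mice, the odds ratio was 1.91 (0.877 to 3.74), and in young soleus 2.65 (0.660 to 7.88). These decide neither way, and the hypothesis stays open.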
